A study of Homo sapiens with 6 samples.

How the data were processed

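The data are gene counts from RNA sequencing of total RNA of OCI-AML3 cells, 3 libraries with a control siRNA and 3 with an siRNA against mutant NPM1, collected on day 3. The authors deposited 1 table of raw counts per gene, whole numbers without normalization, keyed by Entrez gene identifiers. The submitters' processing notes name CASAVA 1.8, cutadapt 2.6, STAR 2.7.5a and DESeq2 1.34.0 and the builds hg38 and mm10. The roles of these tools and builds, the counting tool, its annotation, its strand setting and its handling of reads that fit several places were not given in the sources used here. Counts of overlapping or near-identical genes (rRNA and 7SL copies, histone and HLA genes, genes with processed pseudogenes) can therefore be split or merged in unknown ways. Columns were assigned to samples through the column names that the labels give, and the group and replicate number of each sample came from its title.

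The table held 28307 genes, of which 28261 were matched to a symbol through NCBI RefSeq gene tables (GRCh38.p14) and 46 were not. Totals per library were 15075235 to 25190122 counts. Before replicates were averaged, pairs of libraries were compared by a chi-square of their counts over genes with at least 20 counts in the pair together. Within groups the chi-square per degree of freedom was 1.46 to 2.36, above the sampling noise, so no library was counted as a copy of another. Between groups it was 23.9 to 38.5.

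Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passed filterByExpr at its defaults (a minimum count of 10 and a minimum total of 15). Libraries were scaled by TMM, and the groups were compared by edgeR's quasi-likelihood test (glmQLFit with robust = TRUE, glmQLFTest), two-sided, with Benjamini-Hochberg adjustment. The direction is siNPM1c minus siControl, and a gene counts as called at an adjusted p under 0.05. Standard errors are the absolute log2 fold change divided by the square root of the quasi-likelihood F. The common biological coefficient of variation was 2.17%. CPM values (counts scaled to the TMM-adjusted library size) are given with SD over 3 libraries. GC content is the median over the GENCODE 29 transcripts of a gene, and 97.1% of the tested genes had a value.

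The design, the rule for named genes, 39 gene lists with 897 entries and 18 alternatives were chosen before the data were examined. Lists with at least 5 tested members, 35 in all, were tested with camera of limma 3.58.1 on log-CPM with a prior count of 2 and the preset correlation of 0.01, and 17 were called, 8 upward and 9 downward. Of these, 2 calls held with an estimated correlation, those of the interferon and the G2/M list. With that setting p rose even where the estimate lay below the preset, as for the interferon list (-0.0236). A lost call therefore need not reflect correlation among members. For each list the members called over all genes tested and those called when adjusted over the list alone were counted.

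Genes were named by this rule: NPM1, with its count in every library; the 10 largest increases and 10 largest decreases among genes with an adjusted p under 0.05, a mean of at least 5 CPM and groups that did not overlap, without clone or LOC identifiers; the 5 smallest adjusted p in each direction under the same conditions; up to 3 members with the smallest p of each called list, and 1 of each other list, if called; and MEIS1, PBX3, KAT7, EP300, HOXA9, HOXA10, HOXB4 and HOXB8 whatever their p, with the other HOXA and HOXB genes as a count and range. The rule gave 96 genes, of which 2 are not reported here. HOXA5, HOXB7, HOXB13, IRF9, RN7SL2 and RMRP, named beside them, were chosen after their values were seen.

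The method was tested on simulated counts for the real genes and library sizes with 50 genes changed by each of 4 fold sizes. Every gene was drawn with the common dispersion, as many changed genes were raised as lowered, and no difference in rRNA share was built in. The real comparison called 42.7% of genes and had different rRNA shares, so the rates below hold only for the simulated setting. In that simulation of siNPM1c against siControl, run on 13094 genes, the test recovered 50% of genes changed 1.25-fold, 85.4% of the 48 tested genes changed 1.5-fold, 92% of those changed 2-fold and 100% of those changed 4-fold, and 8 of 170 calls were unchanged genes.

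The alternatives were DESeq2 size factors in the edgeR fit, upper-quartile factors, library sizes alone, no filter beyond 1 count, a filter of 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, glmQLFit with robust = FALSE, the replicate number as a block, leaving out each library, and for the lists also an estimated correlation, fry and a prior count of 0.5. After the data had been seen 5 more were added: leaving out structural RNA genes before scaling, protein-coding genes only, a correction of each library's trend with GC content (lowess, span 0.3, as an offset), a test against a 1.5-fold change (glmTreat), and an assumed biological coefficient of variation of 0.1. Values per person do not arise, since all libraries are of 1 cell line.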

Results

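RNA sequencing was carried out on OCI-AML3 cells, an established human acute myeloid leukaemia line that carries a mutant NPM1 allele whose protein is held in the cytoplasm (NPM1c). The cells were transfected with an siRNA against NPM1c or with a control siRNA, each at a final concentration of 10 nM, and were collected on day 3. Each group held 3 libraries. Total counts per library ran from 15075235 to 25190122, and both groups spanned nearly the same range. Ribosomal RNA genes took 63.8% ± 0.75 (SD, n = 3) of the counts in the siControl libraries and 70.2% ± 0.81 in the siNPM1c libraries. Genes of 7SL, the RNA of the signal recognition particle, took 4.24% ± 0.23 and 4.98% ± 0.25. Protein-coding genes took 28.5% ± 0.46 and 21.8% ± 0.495, which left 3414688 to 6695652 counts per library for them. For each of these 3 shares the groups did not overlap, and an exact two-sided permutation test of 3 against 3 libraries cannot give a p below 0.1.

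**Figure D1:**
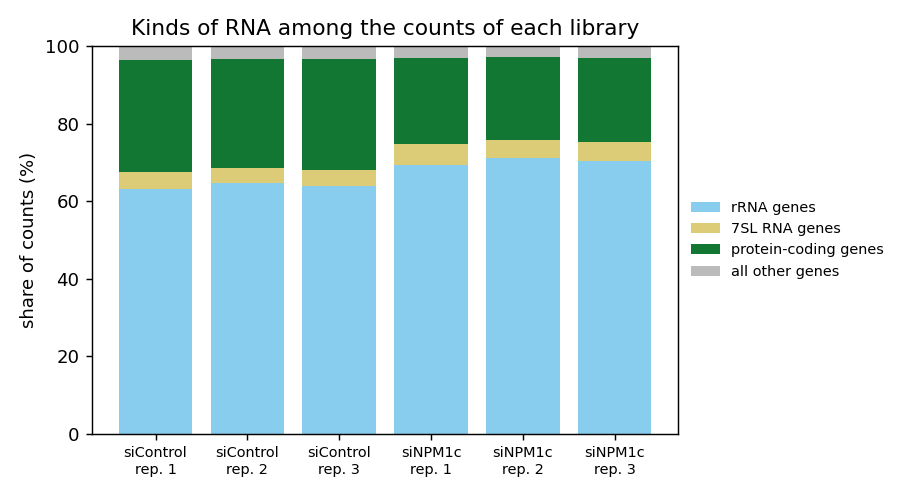
Share of the counts of each library (vertical axis, percent) taken by rRNA genes, 7SL RNA genes, protein-coding genes and all other genes, with 1 bar per library. The rRNA share lay between 69.4% and 71.1% in the siNPM1c libraries and between 63.0% and 64.5% in the siControl libraries.

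The comparison asked which transcripts differed on day 3 between cells given the NPM1c siRNA and cells given the control siRNA. NPM1, the gene of the nucleolar chaperone nucleophosmin (Entrez gene 4869, chromosome 5, 171387116 to 171411137 in GENCODE 29 on GRCh38), was the target. Its raw counts were 922, 1366 and 922 in the siControl libraries and 293, 500 and 350 in the siNPM1c libraries. NPM1 was thereby 2.15-fold lower in the siNPM1c libraries, at 23.2 ± 1.03 CPM (SD, n = 3) against 50.1 ± 0.985 CPM, with a log2 fold change of -1.10 ± 0.05 (SE) and an adjusted p of 5.82e-51 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Transcripts of the mutant and the wild-type allele were counted together, and reads of NPM1 can also fit its processed pseudogenes.

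Of 12938 genes tested, 2756 were higher and 2766 lower in the siNPM1c libraries at an adjusted p under 0.05. An absolute log2 fold change of at least 1 was reached by 293 of the higher and 205 of the lower genes. The groups did not overlap in 49.2% of the genes tested, where chance gives 10%. Directions are relative to TMM scaling, which takes the bulk of genes as level. With library sizes alone, in which the larger rRNA share of the siNPM1c libraries counts as depth, the median gene moved by -0.47 log2, and 505 genes were higher against 9253 lower. The changes are therefore given relative to that shift. Under library sizes alone the sign turned for 10 genes named here, which were CFLAR, ADAR, AZU1, HDAC4, CREBBP, CD74, TNFAIP3, BTG2, RPPH1 and LMO2. Fold changes also followed GC content, with a median log2 fold change of -0.22 over the 2512 tested genes of lowest GC content and 0.09 over the 2511 of highest. Nothing in the labels says that the 3 replicates of a group came from separate cultures. The p-values of single genes therefore measure only the spread between these libraries, which may be technical. Those of lists come from camera, which compares members with the other genes, and measure no spread between cultures either.

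The HOXA and HOXB genes, clustered homeobox genes that mark the stem-like expression state of NPM1-mutant leukaemia, fell together. In the HOXA cluster on chromosome 7, 8 of 8 tested genes fell, with a median log2 fold change of -1.42 and a range from -2.21 for HOXA5 to -0.83 for HOXA10. In the HOXB cluster on chromosome 17, 7 of 9 tested genes fell, with a median of -0.83. These medians became -1.88 for HOXA and -1.30 for HOXB under library sizes alone. The counts adjusted over the list alone were also 8 and 7. HOXA13 fell from 21.5 ± 0.523 to 7.61 ± 1.26 CPM (SD, n = 3), HOXA11 from 38.1 ± 1.79 to 18.0 ± 1.27 CPM, and HOXA10 from 38.0 ± 0.730 to 21.2 ± 1.05 CPM. HOXA9, a driver of leukaemic self-renewal, fell by 0.85 on the log2 scale (SE 0.14), HOXB4 by 0.56 (SE 0.11), HOXB3 by 0.83 (SE 0.09) and HOXB2 by 0.87 (SE 0.15). HOXB8 fell from 4.77 ± 0.686 to 1.09 ± 0.430 CPM, a 4.30-fold decrease. HOXB7 (-0.59 ± 0.32, SE) and HOXB13 (-0.08 ± 0.24) did not pass the test. MEIS1, the homeodomain cofactor of HOXA9, was 2.45-fold lower (-1.30 ± 0.17), and PBX3, a further cofactor, was 1.65-fold lower (-0.72 ± 0.20). The HOXA and HOXB lists were called by camera with adjusted p of 6.79e-06 and 0.000245. Both calls were lost with an estimated correlation (adjusted p = 0.0544 for HOXA and adjusted p = 0.0667 for HOXB). These estimates were -0.0578 for HOXA and -0.0766 for HOXB, below the preset of 0.01. The losses therefore do not reflect correlation among the members. Most HOX genes overlap opposite-strand genes, and because the strand setting of the counting was not given, reads of a gene and of its antisense partner cannot be told apart. Some also overlap on the same strand, as HOXA9 does HOXA10, and HOXB8 and HOXB9 lie within HOXB7. Counts of such neighbours may not be separate.

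**Figure D2:**
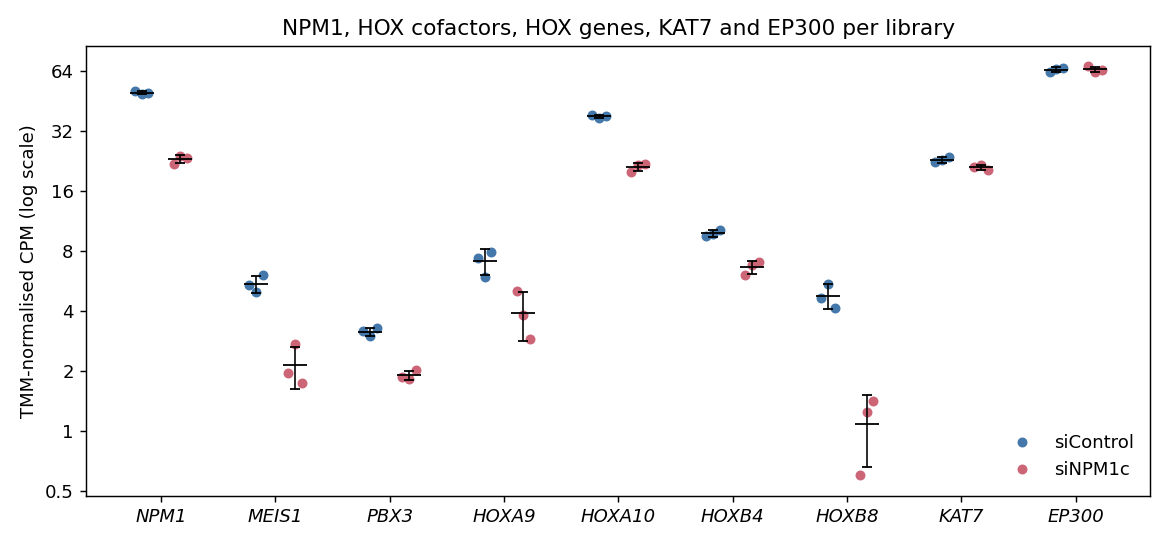
TMM-normalised CPM (vertical axis, log scale) of NPM1, MEIS1, PBX3, HOXA9, HOXA10, HOXB4, HOXB8, KAT7 and EP300 in each library, with points for libraries, long ticks for the mean and bars for the SD (n = 3). NPM1 lay near 50.1 CPM in the siControl and 23.2 CPM in the siNPM1c libraries, while the EP300 means were 65.4 and 65.5 CPM.

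The list of HOX cofactors and targets of menin-KMT2A, the chromatin complex that keeps HOX genes active, held 9 genes that fell and 3 that rose among 15 tested, and the same numbers when adjusted over the list alone. SATB1, a chromatin organiser, fell by 0.79 on the log2 scale (SE 0.04), the adhesion receptor gene ADGRA3 by 1.12 (SE 0.08) and the condensin gene SMC4 by 0.66 (SE 0.05). Camera called the list with an adjusted p of 0.0196, and the call was lost with an estimated correlation (adjusted p = 0.218), with library sizes alone (adjusted p = 0.0524) and with a GC correction chosen after the data had been seen (adjusted p = 0.107).

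Interferon-stimulated genes rose more than any other list by median. Of 36 tested members of the type I interferon list, 34 rose and 0 fell, both over all genes tested and adjusted over the list alone, with a median log2 fold change of 1.20 that became 0.73 under library sizes alone. ISG15, a ubiquitin-like modifier induced by interferon, rose 4.84-fold from 66.5 ± 1.93 to 323 ± 3.73 CPM (SD, n = 3). IFI6 rose 3.28-fold, from 153 ± 2.24 to 504 ± 7.39 CPM, and OAS3, an oligoadenylate synthetase that senses double-stranded RNA, rose 2.95-fold, from 112 ± 5.83 to 329 ± 4.92 CPM. IFI27 rose 4.04-fold, IFITM1, a membrane protein that restricts virus entry, 5.73-fold, the exonuclease gene ISG20 5.42-fold, IFIT2 4.14-fold and OASL 3.85-fold. Reads of IFITM1 can also fit its near-identical neighbours. The log2 fold change of IRF9 was -0.00 ± 0.06 (SE). The list was called with an adjusted p of 4.85e-24, and the call held with an estimated correlation (adjusted p = 0.00916).

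Genes of MHC class I presentation, which displays peptides to T cells, rose with them, 15 of 18 tested and 0 lower by both counts, with a median of 0.52 that became 0.05 under library sizes alone. HLA-B rose 1.72-fold and HLA-C 1.67-fold, although reads of these near-identical genes can be divided among them. Camera gave an adjusted p of 1.33e-08 (adjusted p = 0.0544 with an estimated correlation). Among 15 tested genes of double-stranded RNA and DNA sensing, 8 rose and 1 fell by both counts, with a median of 0.29 that became -0.18 under library sizes alone. EIF2AK2, the RNA-activated kinase PKR, rose by 0.72 ± 0.04 log2 (SE), the RIG-I-like receptor gene DHX58 by 0.98 ± 0.07 and the RNA-editing enzyme gene ADAR by 0.33 ± 0.02, with -0.14 for ADAR under library sizes alone. Camera gave an adjusted p of 0.00775 (adjusted p = 0.101 with an estimated correlation).

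Monocyte and macrophage markers rose on balance, 14 of 23 tested genes higher and 5 lower by both counts, with a median of 0.48 that became 0.01 under library sizes alone. LYZ, the gene of lysozyme, had the smallest p of all genes and rose 5.01-fold, from 80.2 ± 0.805 to 401 ± 8.35 CPM (SD, n = 3). CSF1R, the receptor for macrophage colony-stimulating factor, rose 4.09-fold and the transcription factor gene IRF8 1.64-fold. Camera gave an adjusted p of 0.00139 (adjusted p = 0.11 with an estimated correlation). Granulocyte markers, with 7 of 13 tested genes higher and 3 lower by both counts, had a median of 0.32 that became -0.15 under library sizes alone. PRTN3, the gene of the neutrophil serine protease proteinase 3, rose 2.95-fold, FUT4 1.77-fold and AZU1 1.37-fold, with a log2 fold change of -0.01 for AZU1 under library sizes alone. This list had an adjusted p of 0.0499 (adjusted p = 0.359 with an estimated correlation), and the call was also lost without siControl replicate 3 (adjusted p = 0.0734), without siNPM1c replicate 1 (0.0783) and without siNPM1c replicate 2 (0.059), and in 5 further settings, among them the filter of 5 CPM (0.205) and the GC correction (0.143).

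Myeloid transcription factor genes rose, 17 of 22 tested and 2 lower over all genes tested, and 18 and 2 adjusted over the list alone. Their median was 0.44, and -0.03 under library sizes alone. SPI1, the master regulator PU.1 of myeloid cells, rose 1.56-fold, JUN 1.60-fold and JUNB 1.45-fold, a call lost for JUNB under library sizes alone (0.07 log2). Camera gave an adjusted p of 5.6e-07 (adjusted p = 0.0544 with an estimated correlation). Immediate early genes, which respond within minutes to growth signals and to handling of cells, moved with them. Of 16 tested, 14 were higher and 0 lower by both counts, with a median of 0.63 that became 0.16 under library sizes alone. Whether handling of the cells raised these genes was not tested. FOSL2 rose by 0.58 ± 0.03 log2 (SE), IER3 2.71-fold and IER2 1.46-fold, a call lost for IER2 under library sizes alone (0.07 log2). The list had an adjusted p of 3.81e-07 (adjusted p = 0.0667 with an estimated correlation). The myeloid list above also held immediate early genes, namely JUN, JUNB, FOS, FOSB, ATF3, EGR1, EGR2 and NR4A1. Its rise is therefore not that of lineage factors alone. NF-kB and inflammatory genes rose, 18 of 24 tested and 1 lower by both counts, with a median of 0.34 that was -0.13 under library sizes alone. The chemokine gene CCL5 rose 1.66-fold, IL1RN, the antagonist of the interleukin-1 receptor, 1.86-fold and TNFAIP3, a brake on NF-kB, 1.38-fold, with a log2 fold change of -0.00 for TNFAIP3 under library sizes alone. The list had an adjusted p of 6.07e-06 (adjusted p = 0.057 with an estimated correlation).

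Further genes with large increases were SLPI, an inhibitor of leukocyte proteases, which rose 8.60-fold to 11.8 ± 1.21 CPM (SD, n = 3), and RIN2, a regulator of endosomal Rab GTPases, which rose by 2.07 ± 0.13 log2 (SE). The largest decreases among genes with a mean of at least 5 CPM and separate groups were those of IGFBP5, which binds insulin-like growth factors and fell 3.01-fold from 35.1 ± 0.876 to 11.6 ± 0.593 CPM, and of HOXA13. HOXB-AS3, a noncoding transcript of the HOXB cluster, was 2.43-fold lower, the receptor pseudokinase gene PTK7 2.39-fold, the actin-binding protein gene SYNPO 2.30-fold, the glycoprotein hormone gene STC1 2.24-fold, TP53INP2, a regulator of autophagy, 2.23-fold, the histone gene H3C1 2.18-fold and FAM135B 2.16-fold. The homeobox gene UNCX fell from 140 ± 2.38 to 68.2 ± 3.40 CPM. Smaller decreases with very small spread were found for BAHCC1, a chromatin protein gene (-0.67 ± 0.02 log2, SE), SCD, the fatty acid desaturase (-0.59 ± 0.02), and HSPA8, a constitutive chaperone (-0.73 ± 0.03).

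Genes of the G2/M phase, which drive mitosis, fell, 24 of 30 tested and 0 higher over all genes tested. Adjusted over the list alone these were 25 and 0. The median was -0.44, and -0.91 under library sizes alone. CDK1, the mitotic kinase, fell from 5.24 ± 0.207 to 2.05 ± 0.381 CPM (SD, n = 3), and TOP2A, a topoisomerase of dividing cells, and BIRC5, the gene of survivin, fell by 0.69 (SE 0.06) and 0.51 (SE 0.05) on the log2 scale. The median GC content of the G2/M genes was 42.9%, and with the GC correction their median log2 fold change was -0.34. Camera gave an adjusted p of 2.36e-08, and the call held with an estimated correlation (adjusted p = 0.0425). S phase genes fell, 15 of 30 tested and 0 higher over all genes tested, and 16 and 0 adjusted over the list alone. Their median was -0.21, and -0.68 under library sizes alone. PCNA, the replication clamp, fell 1.89-fold, E2F8 1.56-fold and the helicase subunit gene MCM6 1.33-fold, and the list had an adjusted p of 0.000902 (adjusted p = 0.16 with an estimated correlation).

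In the list of replication-dependent histones and structural RNAs, 28 of 36 tested genes fell and 5 rose by both counts. The median was -0.39, and -0.85 under library sizes alone. The 5 that rose were structural RNAs, among them the near-identical RN7SL1 and RN7SL2, while RMRP, the RNA of RNase MRP, fell by 0.12 (SE 0.02) on the log2 scale. RN7SL1 rose 1.60-fold, SCARNA2, a guide RNA of Cajal bodies, 1.48-fold and RPPH1 of RNase P 1.27-fold, with a log2 fold change of -0.12 for RPPH1 under library sizes alone. By share of all counts, the 7SL genes went only from 4.24% to 4.98%. Histone transcripts have near-identical copies, so the values of single histone genes are uncertain. Camera gave an adjusted p of 2.45e-06 (adjusted p = 0.0802 with an estimated correlation). Ribosomal protein genes fell, 28 of 43 tested with 5 higher over all genes tested, and 29 and 5 adjusted over the list alone. Their median was -0.25, and -0.72 under library sizes alone. RPLP0 fell 1.52-fold, RPL7 1.69-fold and RPL4 1.55-fold, with reads that can also fit processed pseudogenes. The list had an adjusted p of 6.35e-06 (adjusted p = 0.101 with an estimated correlation). Ribosome biogenesis genes fell on balance, 15 of 35 tested with 3 higher by both counts. Their median was -0.15, and -0.62 under library sizes alone. The nucleolar helicase gene DDX21 fell by 0.51 (SE 0.09), the small-subunit processome gene HEATR1 by 0.41 (SE 0.08) and the RNA polymerase I subunit gene POLR1C by 0.63 (SE 0.13) on the log2 scale. This list had an adjusted p of 0.0165 (adjusted p = 0.101 with an estimated correlation).

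Among DNA methylation and other regulators mutated in leukaemia, 8 of 22 tested genes fell and 1 rose over all genes tested. Adjusted over the list alone these were 9 and 1. The median was -0.12, and -0.59 under library sizes alone. The corepressor gene BCOR fell by 0.52 (SE 0.04), the cohesin gene RAD21 by 0.61 (SE 0.07) and the metabolic enzyme gene IDH1 by 0.37 (SE 0.05) on the log2 scale. The adjusted p was 0.0499 (adjusted p = 0.25 with an estimated correlation). It was 0.0613 without siControl replicate 1, 0.0629 without siControl replicate 3, 0.0783 without siNPM1c replicate 1 and 0.116 without siNPM1c replicate 2, where the median was -0.09, and 0.133 with the GC correction. Without siNPM1c replicate 3 the median was -0.21 and the call was kept. It was 0.052 with DESeq2 size factors, 0.0695 with protein-coding genes only and 0.0505 with a prior count of 0.5.

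**Figure D3:**
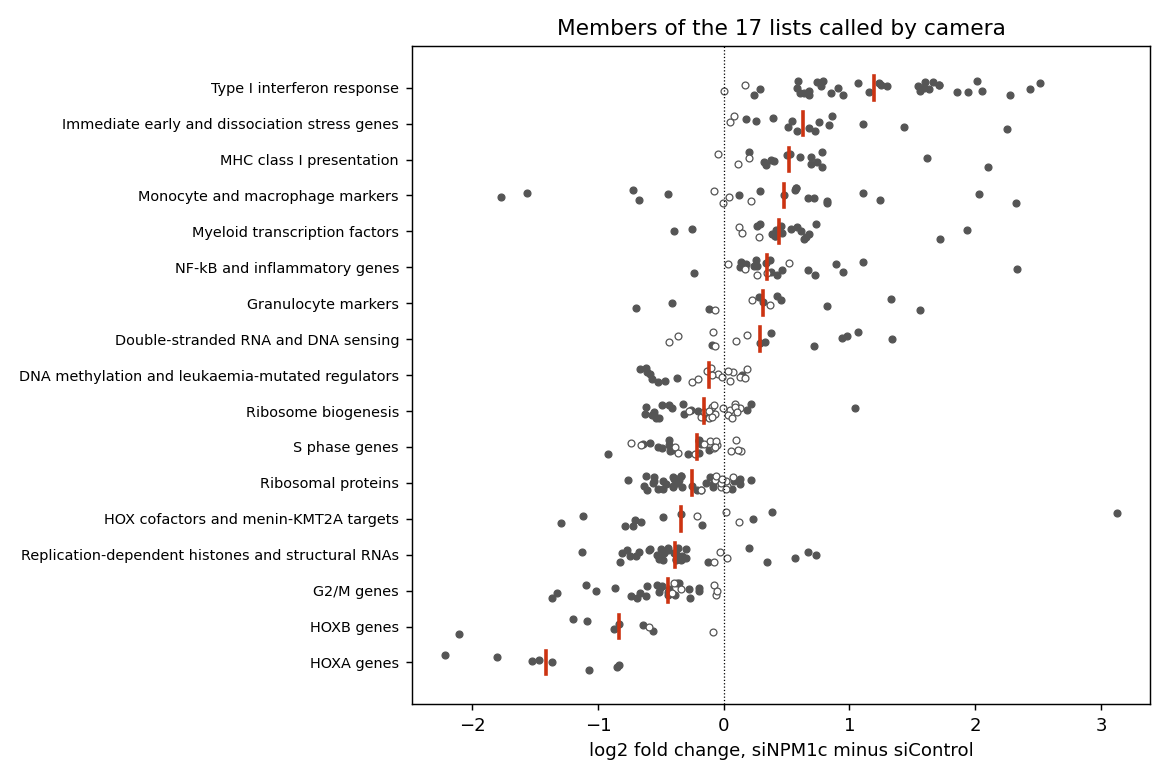
Log2 fold change, siNPM1c minus siControl (horizontal axis), of the tested members of the 17 lists called by camera at its preset correlation, with filled points for genes with an adjusted p under 0.05, open points for the rest and a red line at the median. The medians ran from -1.42 for the HOXA genes to 1.20 for the interferon list.

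The title of the series names the histone acetyltransferases KAT7 and p300. The log2 fold change of KAT7 was -0.12 ± 0.07 (SE, n = 3 per group; edgeR quasi-likelihood adjusted p 0.129) and that of EP300, the gene of p300, was -0.00 ± 0.04 (adjusted p 0.949). Under library sizes alone both were called lower, at -0.59 and -0.47, against the shift of -0.47 in the median gene. In the list of the KAT7 complex with p300 and CBP, 1 of 12 tested genes was higher and 1 lower over all genes tested, and 1 and 0 adjusted over the list alone, with a median of 0.07. CREBBP, the paralogue of EP300, rose by 0.26 ± 0.05 log2 (SE), was at -0.21 under library sizes alone, and lost its call with an assumed biological coefficient of variation of 0.1 (edgeR adjusted p 0.115). Among other lysine acetyltransferases, 2 of 12 were higher and 3 lower, and 4 and 4 adjusted over the list alone. GTF3C4 fell by 0.34 (SE 0.08) on the log2 scale, a call lost with the same assumed coefficient (edgeR adjusted p 0.0612). Among histone deacetylases, which remove the acetyl marks, 6 of 18 were higher and 3 lower, and 6 and 4 adjusted over the list alone, and HDAC4 rose by 0.33 ± 0.03, and was at -0.14 under library sizes alone. Neither these 3 lists nor the menin-KMT2A, DOT1L and elongation machinery (5 of 19 higher and 4 lower by both counts) was called, and DOT1L, the methyltransferase of H3K79, rose by 0.51 ± 0.03, a call lost under library sizes alone (0.04).

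The other lists were not called by camera, whose adjusted p over all lists not called ran from 0.113 to 0.943. In the list of NPM family and nucleolar partners, 3 of 16 genes were higher and 4 lower by both counts. MYC and its targets had 4 of 28 higher and 11 lower by both counts, and the lactate dehydrogenase gene LDHA fell by 0.65 (SE 0.04) on the log2 scale. Cholesterol synthesis had 13 of 24 higher and 4 lower, while its early enzyme HMGCS1 fell by 0.81 (SE 0.04). Cholesterol efflux and lysosomal genes had 6 of 24 higher and 5 lower. The integrated stress response had 12 of 28 higher and 7 lower, and the sestrin gene SESN3 rose by 0.73 ± 0.06. The heat shock response had 5 of 16 higher and 7 lower. Glycolysis and hypoxia genes had 9 of 28 higher and 15 lower, and GAPDH fell by 0.30 (SE 0.02). In oxidative phosphorylation 7 of 33 were higher and 10 lower, and ATP5F1B fell by 0.33 (SE 0.03). Among p53 targets 5 of 27 were higher and 7 lower, and the antiproliferative gene BTG2 rose by 0.37 ± 0.03 (-0.10 under library sizes alone). Among apoptosis regulators 5 of 22 were higher and 4 lower, and the caspase-8 inhibitor gene CFLAR rose by 0.45 ± 0.04 (-0.02 under library sizes alone). In the RNA interference machinery 1 of 14 was higher and 4 lower, and TNRC6A fell by 0.57 (SE 0.10). Stem and progenitor genes had 4 of 11 higher and 4 lower, and LMO2 rose by 0.28 ± 0.04 (-0.19 under library sizes alone), a call lost with the assumed coefficient of 0.1 (edgeR adjusted p 0.0775). All these counts were unchanged when adjusted over the list alone. Adhesion and migration genes had 6 of 17 higher and 6 lower, and 7 and 6 adjusted over the list alone, and the chemokine receptor gene CXCR4 fell by 0.51 (SE 0.06).

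Among markers of other cells, 3 of 6 tested lymphoid genes were higher and 1 lower, and the B cell transcription factor gene PAX5 rose from 0.644 ± 0.223 to 2.99 ± 0.229 CPM (SD, n = 3). Lists with under 5 tested members were only counted. In the erythroid and megakaryocyte list 1 of 4 was higher, VWF, which rose from 0.432 ± 0.179 to 1.64 ± 0.220 CPM. In the MHC class II list 1 of 2 was higher, CD74, at 15.3 ± 1.94 against 19.7 ± 1.65 CPM, with a log2 fold change of -0.10 under library sizes alone. In the stromal, endothelial and epithelial list 2 of 4 were higher, among them FN1, at 6.87 ± 0.510 against 13.4 ± 0.907 CPM. The counts for these 4 lists were the same adjusted over the list alone. The list of mitochondrially encoded genes was not analysed here. Median and test differed in sign for adhesion genes (median -0.01, test upward) and p53 targets (median -0.03, test upward), median and mean for other acetyltransferases (0.12 and -0.01) and for erythroid markers (-0.04 and 0.42).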

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

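The 5 alternatives of structural RNA genes left out, protein-coding genes only, GC correction, a test against a 1.5-fold change and an assumed biological coefficient of variation were chosen after seeing the data. All 96 named genes kept their side of the threshold in every alternative chosen beforehand that tested them except library sizes alone, and the 94 called ones also their direction. EP300, not called, took either sign, from -0.0267 to 0.0809 over the alternatives other than library sizes alone, and 4 genes were not tested with the filter of 5 CPM. NPM1 ran from -1.12 to -0.92 over the alternatives other than library sizes alone. With library sizes alone 9758 genes were called, 505 higher and 9253 lower, and 1357 with an absolute log2 fold change of at least 1 (102 higher, 1255 lower), because the scale itself moved by -0.47. The log2 fold changes of CFLAR (-0.0217), ADAR (-0.14), AZU1 (-0.0144), HDAC4 (-0.14), CREBBP (-0.21), CD74 (-0.10), TNFAIP3 (-0.00106), RPPH1 (-0.12), LMO2 (-0.19) and BTG2 (-0.10) turned there. Of 498 genes with an absolute log2 fold change of at least 1 (293 higher, 205 lower), no filter gave 789 (488 higher), with more genes tested, and the filter of 5 CPM gave 126 (95 higher, 31 lower), with fewer. DESeq2 called 3831 genes against 5522, with 2077 higher against 2756 and 1754 lower against 2766, and the cause was not tested. By construction, the test against a 1.5-fold change called fewer, 441 (312 higher, 129 lower), of which 288 had an absolute log2 fold change of at least 1 and 81 of these were lower, and 41 named genes lost their call. An assumed coefficient of 0.1 gave 3166 calls (1549 higher, 1617 lower), and 3 named genes, CREBBP, GTF3C4 and LMO2, lost their call. Of 17 lists, 2 were called with an estimated correlation, while fry, which compares with no other genes, called 28. At the preset correlation 14 lists kept their call in every alternative that tested them (HOXA and HOXB were not tested with the filter of 5 CPM). Leaving out 1 library gave 4631 to 5254 calls (2435 to 2675 higher, 2196 to 2579 lower), 548 to 593 with an absolute log2 fold change of at least 1 (309 to 352 higher, 225 to 264 lower), and 15 to 17 lists. Without siNPM1c replicate 2 the list of DNA methylation and leukaemia-mutated regulators had an adjusted p of 0.116, the largest of these. Depth limits the low genes, such as HOXB7 at 1.14 CPM, where the SE was 0.32.

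With the replicate number as a block 5586 genes were called (2793 higher, 2793 lower), 500 of them with an absolute log2 fold change of at least 1, and 17 lists, and no call of a named gene or list changed. The numbers were not taken as pairing in the main fit, because the labels do not say that they mark a shared culture. The deviations of libraries with the same number correlated by 0.0193, -0.00266 and -0.00408 over all tested genes. Over 1840 higher-expressed genes these were 0.0929, 0.0595 and 0.0385, each the highest for its library. The rRNA share also followed the number, at 63.0%, 64.5% and 63.9% for siControl and 69.4%, 71.1% and 70.2% for siNPM1c. A link between libraries of the same number is therefore not excluded.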

Other observations

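The genes in this paragraph and the next were chosen after their values were seen, and 2 tests, that of opposite-strand genes and that of interferon transcripts, were chosen only after the result was seen, as was the GC correction. HOXA11-AS fell from 22.0 ± 0.824 to 11.9 ± 1.18 CPM (SD, n = 3), HOTTIP, at the end of the HOXA cluster, from 16.7 ± 1.31 to 8.76 ± 0.227 CPM, and HOXA10-AS fell by 1.00 (SE 0.19) on the log2 scale. These noncoding genes were not a fixed list, and counts of HOXA10-AS and HOXA11-AS are not separable from those of overlapping HOXA genes. The homeobox genes ISL2 and LHX2 fell 1.90-fold and 1.67-fold. Among monocyte markers that went against the list, the costimulatory receptor gene CD86 fell 3.42-fold, the chemokine receptor gene CX3CR1 2.96-fold and the proteoglycan gene VCAN 1.65-fold.

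The receptor kinase gene AXL rose from 1.15 ± 0.311 to 7.91 ± 0.893 CPM (SD, n = 3), and SIGLEC1, a macrophage lectin gene, from 270 ± 2.39 to 521 ± 0.411 CPM. CDKN2A, which encodes cell cycle inhibitors, rose 2.50-fold. CCNA1, a cyclin gene among the menin-KMT2A targets, rose 8.73-fold against its list, from 3 counts in each siControl library to 21, 19 and 22. The near-identical RNA45SN2 and RNA45SN3, genes of the ribosomal RNA precursor, took most counts of every library. They rose by 0.61 ± 0.02 and 0.60 ± 0.02 log2 (SE) relative to TMM scaling. Against this scaling, library sizes alone moved the median gene by -0.47 log2. Which scale holds was not tested, so how much of the rise is a shift of scale stays open. By share of all counts, rRNA genes went from 63.8% to 70.2%.

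Fold changes followed GC content, and the tested HOXA and HOXB genes had median GC contents of 54.4% and 56.8%. Tested genes between 53.98% and 59.53% had a median log2 fold change of 0.07, opposite in direction to the HOX genes. After the GC correction the median of the 17 tested genes was -1.12 (SE 0.14 over genes), against -1.07 before, which argues against that trend as the whole cause. The 3 genes with no opposite-strand gene had a median of -1.20 (SE 0.59). They are too few to decide, and HOXB8 among them lies within HOXB7 on the same strand. Reads of HOX genes and of antisense transcripts therefore cannot be told apart.

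Higher interferon-stimulated genes had a median of 1.23 (SE 0.11 over 36 genes) after the GC correction and 1.20 before. Their median GC content was 51.0%, and tested genes between 48.07% and 53.98% had a median log2 fold change of -0.006. The correction could therefore hardly move this list. So small a trend argues against GC content as the whole cause. Sensing of the transfected siRNA, dependent on its sequence, may raise the same genes. Over 21 interferon genes 20 counts were found in the siNPM1c libraries and 35 in the siControl libraries. With 1 siRNA per group and 1 day, this and an effect of lower NPM1 cannot be told apart.

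Lower G2/M genes had a median of -0.34 (SE 0.05 over 30 genes) after the GC correction and -0.44 before, so the trend may account for part but was argued against as the whole cause. Among all 10 splits of the 6 libraries into 3 and 3, the real one called 5522 genes and the highest other 0, with 226 at an unadjusted p under 0.05 in edgeR's quasi-likelihood test. No split but the real one called as many, and 10 splits are too few for a share under 0.05. Every other split put libraries of both treatments in each of its groups, so the difference between treatments widened the spread there. The 0 calls of those splits are therefore no measure of chance.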
